A study of Rattus norvegicus with 24 samples.

How the data were processed

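Gene expression was measured in the dorsal striatum of male Sprague-Dawley rats with RatRef-12 Expression BeadChips, glass slides that carry 12 single-colour Illumina arrays each. Per the labels, the rats had self-administered methamphetamine (METH, a psychostimulant) or were yoked saline animals, which receive saline whenever a paired animal obtains drug. Total RNA of each sample was amplified, labelled with biotin, hybridized and read on a BeadStation scanner, per the labels' protocols and the design text. Every sample had 1 array. Samples were grouped from their titles, which give the treatment and, for METH, the time of death. The 24 arrays form 4 groups of 6: saline arrays and METH arrays taken 2 h after the last session on slide 1, and saline arrays and METH arrays taken 24 h after it on slides 2 and 3, which hold 3 of each. The labels give the saline rats no time of death. Rats killed 1 month after the last session are mentioned in the design text and were not analysed here.

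The authors deposited a table of probe intensity for 22523 probes, which the file header calls raw and non-normalized. Its values had already been background-subtracted, since 26.4% to 31.7% of the values of an array lie below 0. The software used is not given in the sources used here. Beside each intensity the authors deposited a detection score, which the file header calls a detection p-value. Within an array its rank correlation with the intensity in the same line lay between -0.0136 and -0.00495, while the scores of different arrays had a median rank correlation of 0.918. The similarity between arrays was the same from scores as from intensities (correlation 0.997). The scores therefore stand in another probe order than the intensities, and 36.4% to 45.8% of an array's scores lie above 0.95, as for a value of 1 minus p. The sorted scores of each array were accordingly assigned to its sorted intensities, so that the detection p of a probe follows from its rank. The table lacked 1 score, which was set to the median of its array. The authors also deposited a table of log2 values. These were recomputed to within 2.17e-06 as log2 of the intensity floored at 1 minus the median of each probe over the 12 arrays of slide 1 or of slides 2 and 3, with no scaling between arrays. The column medians of that table run from -0.41 to 0.40, and it was used as an alternative.

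Signals were processed in R 4.3.3 with limma 3.58.1. The neqc function corrected the background by normexp with an offset of 16, using negative controls inferred from the detection p, and normalized all 24 arrays together by quantiles on the log2 scale. Probes with a detection p under 0.05 on at least 6 arrays were tested, which left 10354. Levels are these normalized log2 signals and carry no unit that compares different probes. Fold changes are ratios of them, and the offset makes the folds of dim genes smaller than the true ones. Median intensity per array was 8.3 to 17.9 and the 95th percentile 380.7 to 1335. Slide 1 had 8208 to 9428 detected probes per array and slides 2 and 3 had 9375 to 10306. The number of arrays limits the precision. Correlations between arrays were 0.922 to 0.991, and 0 pairs held identical values. The residual SD was 0.250 on slide 1 and 0.175 on slides 2 and 3.

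Gene symbols came from the platform annotation supplied with the series and were updated through a RefSeq table of the assembly GRCr8, which matched 13752 probes. Of all probes, 13793 have 1 symbol, 0 have several and 8730 have none. Of the tested probes, 7505 are named and 2849 unnamed. The named ones stand for 7360 genes, each represented by its tested probe of highest mean. Names can be old, and no genome was used here.

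A single linear model with group means and a term for slide 3 against slide 2 was fitted to all arrays with lmFit and eBayes. Each METH group was compared with the saline arrays of its own slides, and the difference between the effects at 24 h and 2 h was tested as a contrast of contrasts. METH arrays of different slides were not compared directly. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The labels speak of separate groups of rats, so arrays were taken as independent animals. Gene lists (31, with 5 to 60 tested genes each) were tested with camera at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Members were also adjusted over the list alone. Where a gene was below background on every array of a group, its fold is a lower bound, set against the lowest detected signal of each array.

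The gene lists, the comparisons, the tests and most alternatives were fixed before the data were examined. So was the rule for named genes. For each contrast it takes the 10 higher and 10 lower genes of largest change among those past the threshold, or all where fewer pass. Where fewer than 5 pass in a direction, it takes the 5 genes of lowest p there and says that they do not pass. It adds from each list up to 4 members of lowest p that pass when adjusted over the list alone. It always takes Fos, Fosb, Egr1, Arc, Bdnf, Ntrk2, Creb1, Crem, Pdyn, Penk, Drd1 and Drd2 where measured. Unnamed probes are counted only, unless said to have been chosen after their values were seen.

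The fit was tested on simulated data, 10 sets of 10354 probes of which 200 were changed. At 2 h it recovered 72.7% of probes changed 1.5-fold and 96.8% of those changed 2-fold, and 19.6% of its calls were false. At 24 h it recovered 70.3% and 97%, and 3.46% of calls were false. A spread shared by all arrays is too small for the noisier slide 1. Separate fits of the 12 arrays of each comparison had 4.64% false calls at 2 h and 4.55% at 24 h, with 52.3% and 79.6% of the 1.5-fold changes recovered. The contrast of contrasts had 5.48% false calls. All 60 lists shifted by 0.5 (log2) were called at 2 h, and 3 of 177 unshifted lists were called at 24 h. False calls of lists at 2 h, on the noisier slide, are not given. The shift was larger than the mean change of most lists that passed, so it does not show how often lists of their size are called. The simulated noise was independent between probes, so these counts do not test the preset correlation of camera. Relabelled splits of the real arrays gave a median of 3 lists at 2 h and 4 at 24 h. The design had been fixed, so it was kept and the separate fits are given beside it.

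Alternatives covered the background correction, the normalization, the deposited log2 table, the filter on dim probes, separate fits, limma array weights, trended and robust moderation, the slide term, position on the slide, each of slides 2 and 3 alone, other thresholds, other list tests and leaving out each array in turn. Added after the data were seen were variance weights by set of slides, the deposited log2 values centred per array, a filter on mean signal, the mean of the cortex markers as a covariate, lists without the members shared with another list that passed, and the fit without the 2 arrays of lowest weight. For each comparison 100 splits of the arrays within slides were drawn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.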

Results

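Transcript levels in the dorsal striatum, the part of the basal ganglia that receives dense dopamine input, were measured on 24 arrays after 8 days of self-administration. Rats took METH at 0.1 mg/kg per injection in sessions of 15 h. There were 6 METH samples and 6 yoked saline samples on slide 1 for the 2 h time, and 6 of each on slides 2 and 3 for the 24 h time. The series title names transcription driven by phosphorylated CREB, a factor activated by cyclic AMP and calcium signals, as its subject. The comparisons ask which transcripts differ from yoked saline at each time and whether the METH effect differs between the times. The first principal component of the normalized values held 47.1% of the variance and the second held 6.77%. The first separated the sets of slides: arrays of slide 1 lay from 6.21 to 30.2 on it, those of slides 2 and 3 from -31.2 to -14.7.

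At 2 h after the last session, 4 named genes were higher in METH rats. Nmu, which encodes the neuropeptide neuromedin U, rose 2.72-fold, from 6.24 ± 0.26 in saline to 7.68 ± 0.40 in METH samples (log2 level, SD, n = 6 each; adjusted p = 3.15e-05). Nts, the precursor of neurotensin, a peptide that acts on dopamine pathways, rose 2.43-fold from 7.01 ± 0.39 to 8.30 ± 0.74 (n = 6 each; adjusted p = 0.036). Fst, which encodes the activin-binding protein follistatin, rose 1.98-fold from 6.17 ± 0.38 to 7.15 ± 0.23 (n = 6 each; adjusted p = 0.00457). Pnoc, the precursor of the opioid-related peptide nociceptin, rose 1.88-fold from 5.32 ± 0.43 to 6.23 ± 0.24 (n = 6 each; adjusted p = 0.0342). For each of these genes, 6 of 6 METH arrays lay above every saline array of the slide. Saline signal was detected on 5 of 6 arrays for Fst and on 3 of 6 for Pnoc.

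**Figure D1:**
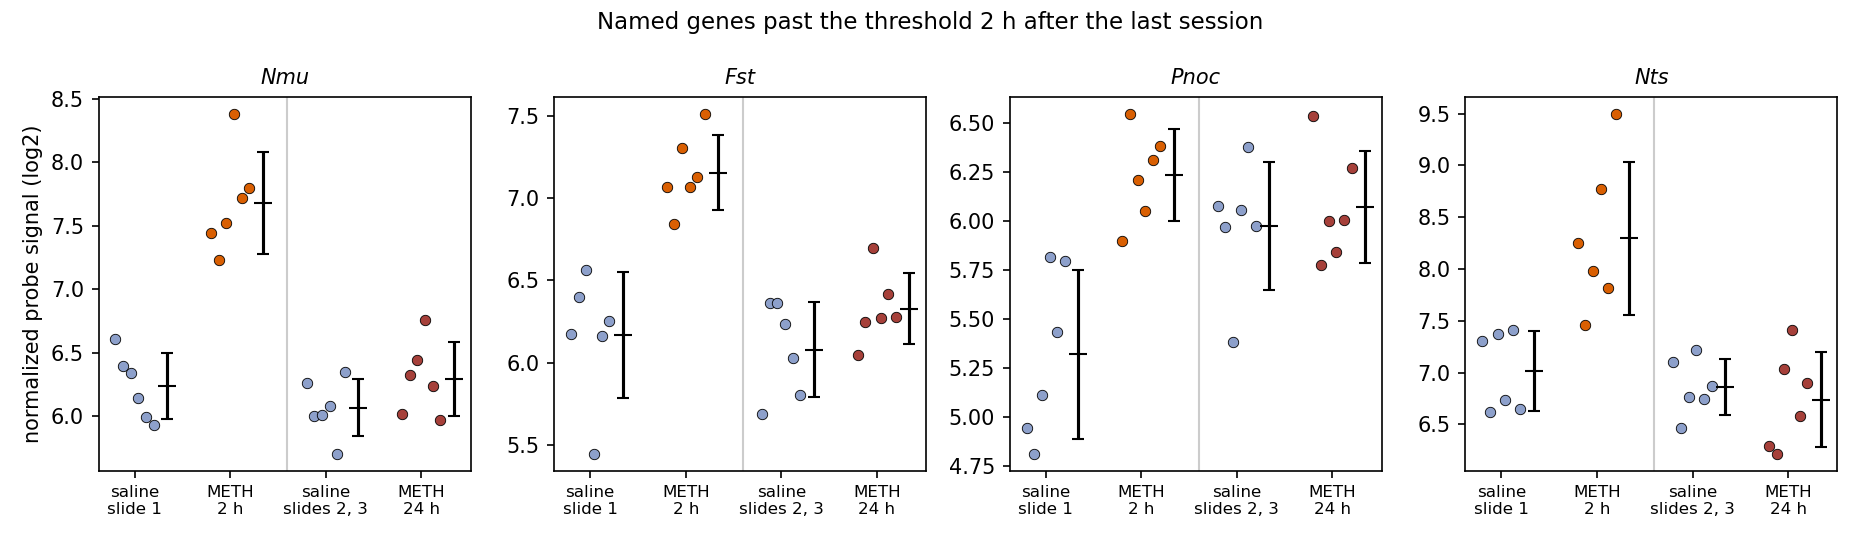
Normalized log2 signal (vertical axis) of Nmu, Fst, Pnoc and Nts on each of the 24 arrays, by group, with n = 6 per group. Points are arrays and bars are the mean ± SD. On slide 1 every METH array lies above every saline array for all 4 genes, and groups to the left and right of the grey line lie on different slides.

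In all, 7 of 10354 probes passed at 2 h, 6 higher and 1 lower, by limma with Benjamini-Hochberg adjustment. The other 3 are unnamed here and had log2 changes of 0.96, 0.65 and -0.72, and are given after their values were seen. At an unadjusted p under 0.05 there were 955 probes against 518 expected by chance. The spread shared by all arrays is too small for slide 1 and raises this count, so the excess is not real changes alone. Nmu alone passed in a separate fit of the 12 arrays, which gave 1 probe, and 6 of 100 splits of the arrays gave as many probes as the real one. The count was 16 without saline replicate 1, 16 without saline replicate 4, 17 without METH replicate 6, 11 without METH replicate 4, and 3 without saline replicate 2 or saline replicate 3. It was 29 without both arrays of lowest weight, saline replicate 4 and METH replicate 6, with Nmu, Fst and Pnoc among them and without Nts. There the cortex markers Slc17a7 (adjusted p = 0.00588) and Neurod6 (0.0282), the clock genes Bmal1 (0.0218) and Nr1d1 (0.035), Efhd2 (0.0218) and Vip (0.03) newly passed over all probes. Slc17a7 (0.0227), Bmal1 (0.0377), Efhd2 (0.0149) and Vip (0.0348) also passed without METH replicate 6 alone. Both Rps9 probes, described with the difference between the times, were among the 17 and the 29 as well. Nmu and Fst passed whichever array was left out. Pnoc did not pass without saline replicate 1, 2, 3 or 5 or METH replicate 2, 3 or 5 (adjusted p 0.0529 to 0.138). Nts did not pass without saline replicate 2, 3, 4 or 6, without METH replicate 1 or 4, or without 1 of 2 arrays on the other slides, their saline replicate 3 and METH replicate 6 (adjusted p 0.051 to 0.138).

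Among the genes that did not pass at 2 h, Efhd2, a calcium-binding protein, had the lowest p of the higher ones, at 1.76-fold (adjusted p = 0.0665; detected on 1 of 6 saline arrays). No named gene passed in the lower direction. The 5 of lowest p there were Upk1a, Nr1d1, Tgfa, Epb41l4a and Plxnd1, with log2 changes between -0.48 and -0.40 and adjusted p of 0.0857 for Upk1a and 0.0919 for the others. Upk1a was detected on 1 of 6 METH arrays. Efhd2 passed without saline replicate 1 (0.0271) or METH replicate 4 (0.0219), without saline replicate 4 (0.0404) or 5 (0.0444) of the other slides, and with slide position (0.0319). Upk1a passed without METH replicate 1 (0.0292). Vip passed without METH replicate 5 (0.0247) and with slide position (0.0167), Nr4a3 without METH replicate 3 (0.0194), and Kcnc2 without METH replicate 4 (0.00762) and in the centred deposited values (0.0416).

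Neuropeptide genes rose as a list at 2 h. Their mean log2 change was 0.41, and of 18 measured members 8 rose and 0 fell when adjusted over the list alone, 2 rose when adjusted over all probes, and 10 did not pass over the list (adjusted p = 2.9e-06, and adjusted p = 0.0516 with an estimated correlation). Besides Nts and Pnoc, the members that passed over the list alone included Vip, the vasoactive intestinal peptide gene, and Pdyn, the precursor of the dynorphins. Vip was below background on all 6 saline arrays and was at least 2.01-fold higher in METH samples (adjusted p = 0.0754 over all probes, 0.000568 over the list alone). Pdyn was 1.43-fold higher (adjusted p = 0.144 and 0.00405). Without the 7 members shared with other lists that passed at 2 h, the neuropeptide list still passed (adjusted p = 0.000533, and 0.163 with an estimated correlation). CREB target and trophic genes also rose as a list, with a mean log2 change of 0.27. Of 16 members, 6 rose and 0 fell adjusted over the list alone and 0 over all probes (adjusted p = 0.000128, and adjusted p = 0.0872 with an estimated correlation). The call is not separate from that of the neuropeptides, since 6 of its members are in both lists. Without the 9 members it shares with other lists that passed at 2 h, it did not pass (adjusted p = 0.0625). Nor did it with the mean of the cortex markers as a covariate (mean 0.14, adjusted p = 0.0904). Examples are Syp, the synaptic vesicle protein synaptophysin, at 1.48-fold, Adcyap1, the PACAP peptide gene, at 1.62-fold, and Nptx2, a secreted pentraxin of excitatory synapses, at 1.43-fold. On the same arrays, markers of cerebral cortex were higher. Their list had a mean log2 change of 0.55, and 7 of 13 members rose adjusted over the list alone and 0 over all probes (adjusted p = 7.6e-05, and adjusted p = 0.252 with an estimated correlation). Without Cck, which is in the neuropeptide list too, it still passed (adjusted p = 0.000533, and 0.252 with an estimated correlation). The mean of the 10 cortex markers in no other list was 0.45 higher (log2) in METH samples (two-sided exact permutation p = 0.0433), with 3 METH arrays above every saline array. Among them Neurod6, a transcription factor of cortical excitatory neurons, was 2.29-fold higher (adjusted p = 0.259; detected on 2 of 6 saline arrays) and Satb1 was 1.63-fold higher (adjusted p = 0.25). Cck, a peptide of cortical cells and interneurons, was 3.22-fold higher with a saline SD of 1.77 (adjusted p = 0.27).

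At the preset correlation 3 further lists passed at 2 h. The list of ER stress and amino acid response genes rose by a mean of 0.11 (log2), with 0 of 26 members past either adjustment (adjusted p = 0.018, and adjusted p = 0.252 with an estimated correlation). It did not pass without saline replicate 1 (adjusted p = 0.177) or METH replicate 1 (0.0584). Synaptic vesicle and release genes rose by a mean of 0.15, with 1 of 20 members, Syp, past the threshold over the list alone and 0 over all probes (adjusted p = 0.0316, and adjusted p = 0.355 with an estimated correlation). Without Syp, Syn1 and Syn2, which are in the CREB target list too, it did not pass (adjusted p = 0.138). That list did not pass without saline replicate 1, 3 or 6 or METH replicate 2 or 5 (adjusted p 0.0508 to 0.143). Markers of striatal projection neurons fell as a list, with a mean log2 change of -0.11. Of 23 members 2 fell and 1 rose over the list alone, and 0 over all probes (adjusted p = 0.0425, and adjusted p = 0.403 with an estimated correlation). The members that fell over the list alone were Itpka, a kinase of inositol trisphosphate, with a log2 change of -0.42 (adjusted p = 0.135 over all probes), and the dopamine D1 receptor gene Drd1, with -0.38 (adjusted p = 0.257). Pdyn was the member that rose. Without Pdyn, Penk and Tac1, which are in other lists that passed, the mean was -0.16 (adjusted p = 0.00397, and 0.252 with an estimated correlation). This list did not pass without saline replicate 2, 3 or 6 or METH replicate 1, 2 or 6 (adjusted p 0.0605 to 0.14). Its mean was 0.07 in the deposited log2 values, 0.10 with median scaling and 0.01 in the deposited values centred per array, where the median change of all probes was 0.20, 0.16 and 0.14. It did not pass in the deposited values (adjusted p = 0.057) or with median scaling (0.0864). With the mean of the cortex markers as a covariate, neither this list (mean -0.05, adjusted p = 0.384) nor the synaptic vesicle list (0.354) passed.

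**Figure D2:**
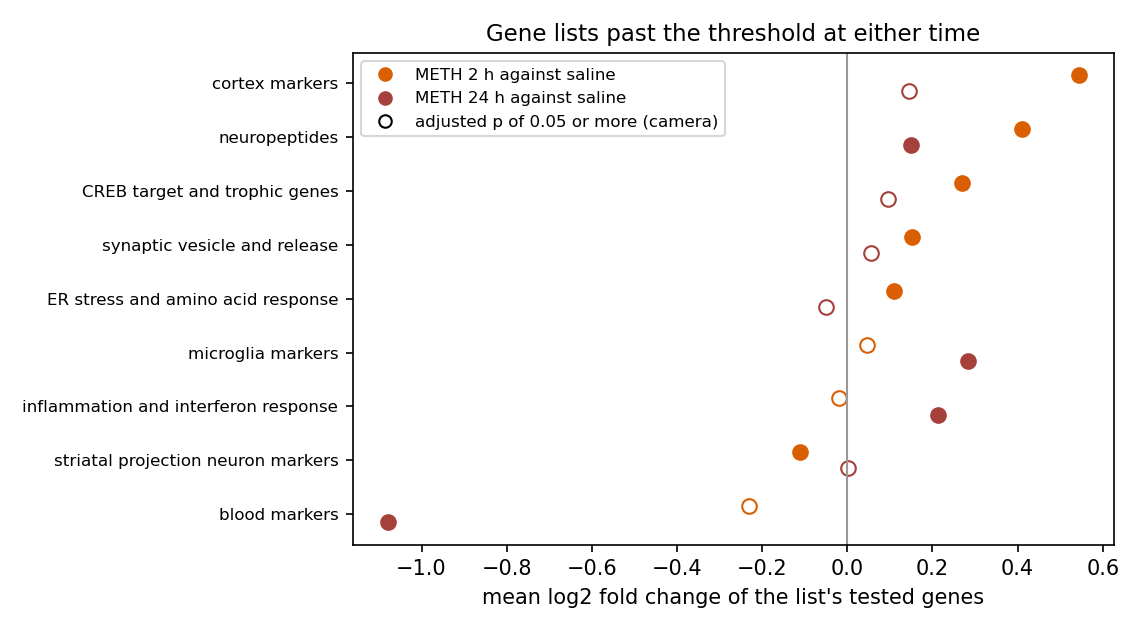
Mean log2 fold change (horizontal axis) over the tested genes of each list past the threshold at 2 h or 24 h, for METH against saline arrays of the same slides, n = 6 per group. Filled points have a camera adjusted p under 0.05 at the preset correlation. Neuropeptides and cortex markers lie farthest to the right at 2 h, and blood markers farthest to the left at 24 h at -1.08.

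The other 25 lists did not pass at 2 h. Immediate early genes, which neurons switch on within minutes of activity, came nearest (adjusted p = 0.0535). Of 31 members 3 rose adjusted over the list alone: Crem, a CREB relative whose short product represses cyclic AMP signalling, at 1.44-fold, the nuclear receptor gene Nr4a3 at 1.51-fold, and Nptx2. None passed over all probes. The list of the CREB pathway itself had an adjusted p of 0.426, striatal interneuron markers 0.0569, heat shock proteins 0.0569, and dopamine synthesis, transport and receptors 0.182. The adjusted p was 0.93 for glutamate receptors and transporters and 0.898 for GABA synthesis, transport and receptors. In these lists Slc17a7 (1.77-fold) and Slc17a6 (1.88-fold), both vesicular glutamate transporters, and the interneuron peptide gene Npy (1.33-fold) rose over the list alone, while the receptor subunit genes Grik5 (log2 change -0.42) and Gabrd (-0.41) fell. Slc17a7 was detected on 2 of 6 and Slc17a6 on 3 of 6 saline arrays. The circadian clock list went both ways (adjusted p = 0.93). Over the list alone its activator Bmal1 rose, with a log2 change of 0.40, and its repressor Nr1d1 and the output factor Tef fell, with -0.47 and -0.37. The labels give no time of death for the saline rats, so a difference in time of day is not separated from METH in these values. Among voltage-gated potassium channels (adjusted p = 0.93), Kcnc2 rose 1.57-fold over the list alone, and its other probes had log2 changes of 0.22 and 0.48. In the choroid plexus and ependyma list (adjusted p = 0.258), Cd24 had a log2 change of 0.37 and rose, and the growth factor gene Igf2 had -0.93 and fell, over the list alone. Cell markers of astrocytes (adjusted p = 0.806), microglia (0.798), oligodendrocytes (0.426), oligodendrocyte precursors (0.635), endothelial cells and pericytes (0.143), thalamus and pallidum (0.252) and blood (0.182) did not pass. Neither did glucocorticoid-responsive genes (0.464), the antioxidant response (0.898), inflammation and interferon response (0.898), chromatin and DNA methylation enzymes (0.93), ubiquitin and proteasome subunits (0.191), cytosolic ribosomal proteins (0.806), oxidative phosphorylation subunits (0.93) or cholesterol synthesis (0.182). The mean and median of the list differ in sign for glutamate receptors (0.04 and -0.04), GABA genes (0.005 and -0.003), cytosolic ribosomal proteins (-0.03 and 0.001) and potassium channels (0.01 and -0.03), and the mean of chromatin enzymes (0.002) and of oxidative phosphorylation subunits (0.005) was above 0 where camera's direction was down.

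Of the genes named in advance, none passed over all probes at 2 h. Fos, a marker of recent neuronal activity, had a log2 change of 0.50 (SE 0.187; adjusted p = 0.355) and Bdnf, a neuronal growth factor, 0.68 (SE 0.214; adjusted p = 0.248; detected on 3 of 6 saline arrays). The dopamine D2 receptor gene Drd2 had -0.33 (adjusted p = 0.418), Egr1 0.15 (0.748), Arc -0.14 (0.897), Penk -0.06 (0.928) and the BDNF receptor gene Ntrk2 0.03 (0.982). At 24 h the log2 changes of Penk (0.21), Pdyn (0.18), Egr1 (0.14), Bdnf (0.12), Arc (0.10), Drd2 (0.08), Ntrk2 (0.07), Drd1 (0.02), Fos (0.01) and Crem (-0.08) all had an adjusted p of 1. Creb1 had no tested probe, and no probe annotated as Fosb was used here.

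At 24 h, transcripts of haemoglobin, the oxygen carrier of red blood cells, were lower in METH rats. Hbb-b1 was 3.47-fold lower, at 8.50 ± 0.49 against 10.29 ± 0.48 in saline samples (log2 level, SD, n = 6 each; adjusted p = 0.000926). Hbb was 3.36-fold lower, at 10.19 ± 0.63 against 11.94 ± 0.52 (n = 6 each; adjusted p = 0.00155). Hba-a1 was 3.22-fold lower, at 10.80 ± 0.59 against 12.49 ± 0.50 (n = 6 each; adjusted p = 0.00584). Hba-a3 was lower too (log2 change -1.51; adjusted p = 0.00155), but it was detected on 2 of 6 METH arrays, so background limits the size of its fall. For each, 6 of 6 METH arrays lay below every saline array. The log2 changes within slide 2 and slide 3 were -1.93 and -1.66 for Hbb-b1, -1.91 and -1.58 for Hbb, -1.78 and -1.59 for Hba-a1, and -1.50 and -1.53 for Hba-a3. Saline levels of Hba-a1 on slide 1 were 11.46 ± 0.47 (n = 6), on a different slide and untested.

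**Figure D3:**
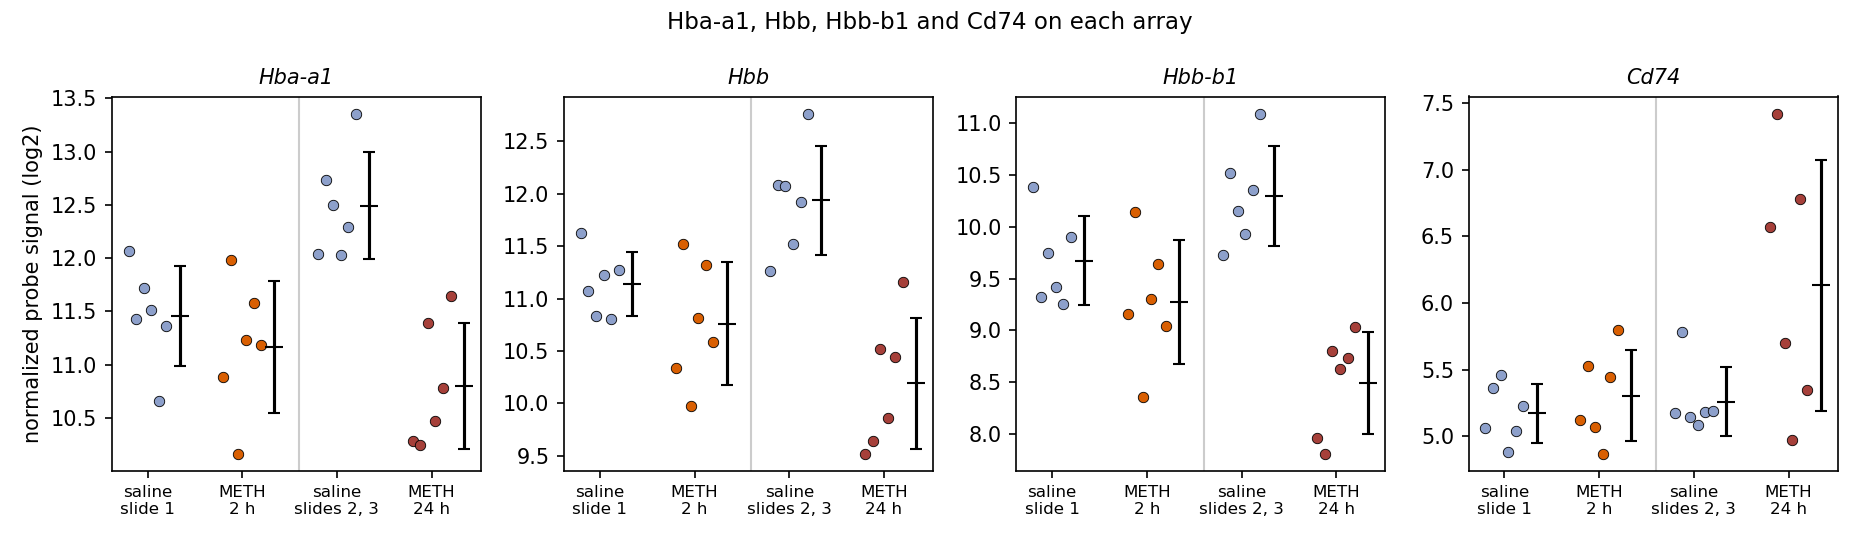
Normalized log2 signal (vertical axis) of Hba-a1, Hbb, Hbb-b1 and Cd74 on each of the 24 arrays, by group, with n = 6 per group. Points are arrays and bars are the mean ± SD. All 6 METH arrays of 24 h lie below the saline arrays of their slides for the haemoglobin genes, and Cd74 spreads more widely among them, with an SD of 0.94.

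In all, 5 probes passed at 24 h, 1 higher and 4 lower, and 201 had an unadjusted p under 0.05 against 518 expected by chance. The spread shared by all arrays is too large for the quieter slides 2 and 3 and lowers the count of 201. That count therefore does not show fewer changes than chance gives. In the simulated data the shared fit recovered 70.3% of 1.5-fold changes at 24 h, and separate fits recovered 79.6%. The higher probe is unnamed, with a log2 change of 2.64 (adjusted p = 0.0149), and follows the Rps9 probes described with the difference between the times. The 4 haemoglobin genes passed in a separate fit of the 12 arrays too, which gave 8 probes. None passed in the deposited log2 values, where the changes were -1.87 for Hbb-b1, -1.79 for Hbb, -1.66 for Hba-a1 and -3.17 for Hba-a3. No other named gene passed. Of the higher ones, those of lowest p were Creg1 (log2 change 0.42, adjusted p = 0.507), and Clec4a3 (0.40), the complement gene C2 (0.88), the chemokine gene Ccl5 (0.78) and Cd74 (0.87), each with an adjusted p of 1. Ccl5 was detected on 2 of 6 saline and 4 of 6 METH arrays. The autophagy gene Atg5 had -0.36 (adjusted p = 0.726; detected on 2 of 6 METH arrays).

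Blood markers fell as a list at 24 h, with a mean log2 change of -1.08. Of 5 measured members 3 fell, both over the list alone and over all probes (adjusted p = 5.84e-18, and adjusted p = 0.000106 with an estimated correlation). These 3 are Hbb, Hbb-b1 and Hba-a1, so the list restates the calls of those genes. Epb42 (-0.12) and Pf4 (-0.03) did not pass. Within slide 2 and slide 3 the mean was -1.10 and -1.05. Markers of microglia, the immune cells of the brain, rose by a mean log2 change of 0.28. Of 18 members 5 rose and 0 fell over the list alone and 0 over all probes (adjusted p = 3.36e-14, and adjusted p = 0.0163 with an estimated correlation). With fry the microglia list did not pass (adjusted p = 0.0985). Examples over the list alone are Cd74, which takes part in antigen presentation, at 1.83-fold, the complement gene C1qb at 1.46-fold and the signalling adaptor gene Tyrobp at 1.30-fold. Within slide 2 and slide 3 the list's mean was 0.36 and 0.21. Genes of inflammation and interferon response rose by a mean of 0.21, with 1 of 13 members, Ccl5, past the threshold over the list alone and 0 over all probes (adjusted p = 0.000102, and adjusted p = 0.202 with an estimated correlation). On slide 2 their mean was 0.34 and on slide 3 it was 0.08 (adjusted p = 0.461). Without METH replicate 2 the mean was 0.10 (adjusted p = 0.108). Neuropeptides rose by a mean of 0.15, with 0 of 18 members past either adjustment (adjusted p = 0.00445, and adjusted p = 0.226 with an estimated correlation). The mean was 0.18 on slide 2 and 0.12 on slide 3 (adjusted p = 0.127). This list did not pass without METH replicate 1 (adjusted p = 0.0799), saline replicate 2 (0.0678) or saline replicate 6 (0.0622).

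The other 27 lists did not pass at 24 h. CREB target and trophic genes and choroid plexus markers came nearest (adjusted p = 0.0584 each), followed by astrocyte markers (0.0808). Over the list alone the astrocyte genes Ndrg2 (1.32-fold) and Aldoc (1.28-fold) rose and the amino acid transporter gene Slc7a10 fell, with a log2 change of -0.40. Cortex markers had a mean of 0.15 (adjusted p = 0.121), with 0.28 on slide 2 (adjusted p = 0.00179) and 0.01 on slide 3 (0.898). Other lists also passed on slide 2 and not on slide 3: immediate early genes (mean 0.19 with adjusted p = 2.18e-05, against -0.09 with 0.0532), glucocorticoid-responsive genes (0.21 with 0.000581, against -0.01 with 0.461), cytosolic ribosomal proteins (0.09 with 0.00104, against -0.01 with 0.653) and choroid plexus markers (-0.65 with 0.00612, against -0.14 with 0.638). Of 100 splits of the arrays, 57 gave at least as many lists as the 4 found. The mean and median of a list differ in sign at 24 h for synaptic vesicle genes, oxidative phosphorylation subunits, projection neuron markers, chromatin enzymes and potassium channels, all with an adjusted p of 0.797 or more. The count of lists was 8 without saline replicate 1 or 3, 7 without saline replicate 4, 10 without saline replicate 5 and 7 without METH replicate 6.

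The METH effect at 24 h minus that at 2 h did not pass for any probe. Each time has its own slides and saline arrays, so an effect of time is not separated from the set of slides. The lowest adjusted p from limma was 0.0758, and 503 probes had an unadjusted p under 0.05 against 518 expected by chance. The count was 3 without saline replicate 3 of slide 1, 4 without METH replicate 6 of slide 1 and 3 without METH replicate 5 of 24 h. All of these probes were higher, and the only named ones were the Rps9 probes described below. Nmu had the lowest p of the lower genes, with a difference of -1.22 (log2; SE 0.234; adjusted p = 0.0758, and 0.0322 with array weights), followed by Cst6 (-0.73), Nipsnap3b (-0.74), the amino acid transporter gene Slc38a2 (-0.63) and Hba-a3 (-1.30). Among the higher, Creg1 had 0.60, Amdhd2 0.51, Upk1a 0.57 and the interferon signalling gene Irf9 0.56. Over their lists alone, Nts (-1.40), Pnoc (-0.81), Hbb-b1 (-1.40), Hbb (-1.37), Hba-a1 (-1.40), Slc7a10 (-0.53) and Gabrd (0.50) differed.

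Rps9, which encodes a protein of the small ribosomal subunit, had the largest difference among the named genes, 2.96 by its brighter probe (SE 0.68; adjusted p = 0.317, and 0.011 over the ribosomal list alone) and 5.92 by its dimmer probe (adjusted p = 0.0758). The brighter probe passed without METH replicate 6 of slide 1 (3.56; adjusted p = 0.000133), without the 2 arrays of lowest weight (3.53; 0.000466) and with array weights (3.30; 0.0193). At 24 h both probes passed in the separate fit. Its signal took either of 2 levels from array to array. It was at the upper level on 5 of 6 saline and 1 of 6 METH arrays of slide 1, and on 0 of 6 saline and 5 of 6 METH arrays of slides 2 and 3. The other 59 measured ribosomal protein genes had a median log2 change of 0.04 at 24 h, against 1.45 for the brighter probe of Rps9.

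**Figure D4:**
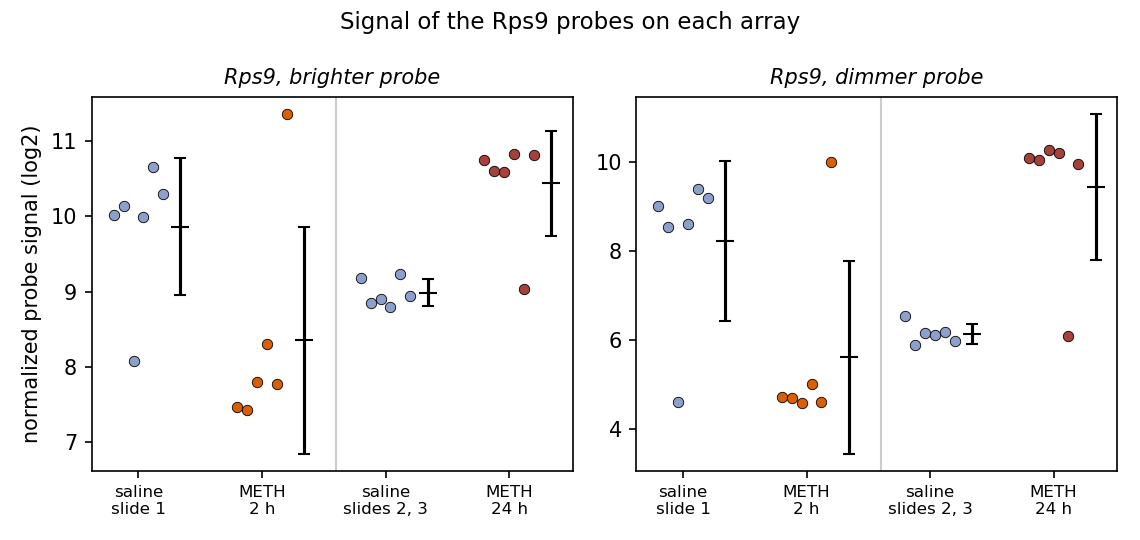
Normalized log2 signal (vertical axis) of the brighter and the dimmer Rps9 probe on each of the 24 arrays, by group, with n = 6 per group. Points are arrays and bars are the mean ± SD, and arrays of 3 groups lie at both levels.

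As lists, 7 differed between the times by camera at the preset correlation, and 0 with an estimated correlation. Lower at 24 h than at 2 h, relative to saline, were blood markers (mean difference -0.85 log2; adjusted p = 0.000193), ER stress and amino acid response genes (-0.16; 0.00157), neuropeptides (-0.26; 0.0198) and cortex markers (-0.40; 0.0198). Higher were microglia markers (0.24; 0.000607), inflammation and interferon response (0.23; 0.0198) and dopamine synthesis, transport and receptors (0.18; 0.0274). The 6 tested members of the dopamine list were Drd1, Drd2, Maoa, Maob, Nr4a2 and Aldh1a1, so its name is wider than what was measured. With an estimated correlation the adjusted p was 0.136 for blood, ER stress and dopamine genes, 0.386 for neuropeptides and microglia, and 0.475 for cortex and inflammation. Members past the threshold over the list alone numbered 3 of 5 for blood, 2 of 18 for neuropeptides and 0 for the others, and 0 over all probes for all of these lists. The mean difference of the dopamine list was -0.04 in the deposited log2 values and -0.07 with median scaling, where the median difference of all probes was -0.23 and -0.19. The mean, the median and the direction of the test differ in sign for glutamate and GABA genes, oligodendrocyte markers, choroid plexus markers, the antioxidant response, chromatin enzymes and potassium channels, all with an adjusted p of 0.94. The count of lists was 4 without METH replicate 1 or saline replicate 2 of slide 1 or saline replicate 4 of slides 2 and 3, 12 without METH replicate 5 of slide 1 and 11 without METH replicate 6 of slide 1. Neuropeptides did not pass without saline replicate 2 or 5 or METH replicate 4 of slide 1, saline replicate 1 or 4 of slides 2 and 3, or METH replicate 2 of 24 h (adjusted p 0.0515 to 0.0976). Cortex markers did not pass without saline replicate 2, 5 or 6 or METH replicate 1 or 2 of slide 1, or saline replicate 4 of slides 2 and 3 (0.0521 to 0.0976). Inflammation genes did not pass without saline replicate 2 or METH replicate 1 or 3 of slide 1, or METH replicate 2 of 24 h (0.0521 to 0.24). Dopamine genes did not pass without saline replicate 6 or METH replicate 1 or 6 of slide 1, or saline replicate 4 of slides 2 and 3 (0.0521 to 0.0606).

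Across the 7360 genes, which are not independent replicates, the log2 changes at 2 h and 24 h had a Pearson correlation of 0.10. Over 100 random relabellings of METH and saline within slides the correlation ran from -0.34 to 0.29, and 47 lay as far from 0 (two-sided permutation p = 0.475). At an unadjusted p under 0.05 at both times there were 15 genes, against 14.9 expected, and 9 of them had the same sign. The comparisons share no control arrays.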

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

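Of the tests reported in this part, the comparison of Rps9 with the size of the change of other ribosomal protein genes, and the tests of METH as the whole cause and of a sequence variant, were chosen after the result was seen.

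The Rps9 probes lay at either of 2 levels, and 3 arrays stood far from the rest of their groups in the brighter probe: saline replicate 3 of slide 1 at 8.07 against 9.99 for the nearest array, METH replicate 6 of slide 1 at 11.36 against 8.31, and METH replicate 5 of 24 h at 9.04 against 10.59 (log2). With the labels of saline replicate 3 and METH replicate 6 of slide 1 exchanged, 0 probes outside this pattern passed at 2 h, against 7 with the labels as given. That argues against a swap of those labels, though weakly. Other splits of slide 1 had a median of 0 probes too, and chance is not excluded for the 7. A change of ribosomal proteins as a class is not borne out either: their median correlation with Rps9 within groups was 0.234, which lay between the bounds set in advance, but the 59 others had a median log2 change of 0.04 at 24 h (quartiles -0.04 and 0.09) against 1.45 for Rps9. Arrays of 3 groups lay on both sides of the gap, 1 of them a saline group, which argues against METH as the whole cause, and how far METH contributes stays open. A sequence variant between rats under these probes cannot be told apart from other causes of 2 levels: the widest gap, 8.79 times the spread within the levels on slide 1 and 19.9 times on slides 2 and 3, only describes the levels it defines, and no sequence was examined.

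Single arrays also stood apart in other named genes. Among the saline arrays of slide 1, replicate 4 was low in Crem (5.73, nearest 6.56), Fst (5.45, nearest 6.16) and Penk (12.01, nearest 12.38), replicate 1 was low in Creg1 (6.39, nearest 6.65), and replicate 5 was high in Igf2 (11.28, nearest 9.86). Among the METH arrays of 2 h, replicate 6 was low in Bmal1 (5.38, nearest 5.95) and Tef (6.56, nearest 7.04), and replicate 5 was high in Slc38a2 (11.67, nearest 11.35). Among the saline arrays of slides 2 and 3, replicate 2 was high in Cd74 (5.78, nearest 5.19) and replicate 5 was high in Drd2 (8.69, nearest 8.32). In all, 13 of 188 groups of values held such an array, where chance gives about 9. Saline replicate 4 of slide 1 and METH replicate 6 of slide 1 had 3 each and also the lowest array weights, 0.355 and 0.410.

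The METH effect differed between 24 h and 2 h for 7 gene lists, by the test of the difference itself at a preset correlation. Time and set of slides coincide, so they cannot be told apart here. The mean difference (24 h minus 2 h, log2) was -0.845 for blood markers, 0.236 for microglia markers, -0.16 for ER stress and amino acid response, -0.259 for neuropeptides, -0.4 for cortex markers, 0.231 for inflammation and interferon response, and 0.184 for dopamine synthesis, transport and receptors. None of them passed with an estimated correlation (adjusted p 0.136 to 0.475). Of 100 splits of the arrays within slides, 12 gave at least 7 lists, and the highest of the others gave 12, so chance is not excluded for this count.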

How the results depend on the processing

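Variance weights by set of slides, deposited values centred per array, the mean-signal filter, the cortex covariate, alone and with an estimated correlation, lists without shared members and the fit without the 2 arrays of lowest weight were chosen after the data were seen. No paired analysis was possible because the labels give no replicate numbers. Where no reason is given, the cause was not tested. The probes past the threshold at 2 h numbered 7. They numbered 2 in the deposited log2 values (1 higher, 1 lower), 3 with median scaling (3 higher, 0 lower), 3 with no filter on dim probes (more probes tested), 2 with a stricter filter (fewer probes tested), 1 in the separate fit, 2 with array weights, 3 with variance weights by set of slides and 3 with the cortex covariate. They numbered 11 with slide position, 12 in the centred deposited values and 29 without the 2 arrays of lowest weight. At looser thresholds there were 74 (unadjusted p under 0.05 and 1.5-fold), 35 (adjusted p under 0.1) and 955 (unadjusted p under 0.05). Without each array in turn the count ran from 3 to 17. Nmu passed in the separate fit, where Fst had an adjusted p of 0.0661, Pnoc 0.142 and Nts 0.212. Fst, Pnoc and Nts also had 0.124, 0.0546 and 0.244 in the deposited values, and 0.0577, 0.0677 and 0.0919 with array weights. The adjusted p of Nmu ran from 1.48e-05 to 0.021 over the alternatives that tested it. The stricter filter removed Nmu, Fst and Pnoc, which were not tested there, and Nts passed (adjusted p = 0.046).

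The probes past the threshold at 24 h numbered 5. They numbered 0 in the deposited log2 values, 2 in the same values centred per array (0 higher, 2 lower), 3 with no filter, 3 with the stricter filter, 3 with trended and robust moderation, 8 in the separate fit and 1 on slide 3 alone (fewer arrays), with 22 and 201 at the looser unadjusted thresholds. Without each array in turn they numbered 4 to 7. On slide 2 alone 4 passed, 1 of them shared with the full set. For the difference between the times 0 probes passed, 4 with array weights, 4 without the 2 arrays of lowest weight, 4 at an adjusted p under 0.1, and 106 and 503 at the unadjusted thresholds. Without each array in turn there were 0 to 4, and the only named ones were Rps9 probes.

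Lists past the threshold at 2 h numbered 6, against 11 with median scaling (8 higher, 3 lower), 11 in the centred deposited values (7 higher, 4 lower), 0 with an estimated correlation, 0 with an estimated correlation and the cortex covariate together, and 2 with fry, and 4 to 9 without each array in turn. At 24 h they numbered 4, against 7 without background correction, 7 in the deposited values, 9 on slide 2 alone and 2 on slide 3 alone. They numbered 2 with an estimated correlation (blood and microglia markers), 1 with fry (blood markers), and 3 to 10 without each array in turn. For the difference they numbered 7, against 4 with median scaling, 4 in the centred deposited values, 1 with no filter, 12 with array weights, 12 without the 2 arrays of lowest weight, 0 with an estimated correlation and 1 with fry, and 4 to 12 without each array in turn. The split at 2 h in the deposited values was 5 higher and 3 lower. The correlation of the effects stayed within its spread under every alternative run, from 0.0386 with median scaling to 0.178 with the cortex covariate, and from 0.0402 to 0.158 without each array in turn.

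The means of 2 lists that passed as planned changed sign with the scaling: projection neuron markers at 2 h (-0.11) were 0.0663 in the deposited values, 0.101 with median scaling and 0.01 in the centred values, and the dopamine list in the difference (0.18) was -0.0446 and -0.0681 in the deposited values and with median scaling. The median of all probes shifted there too, to 0.199, 0.155 and 0.141 at 2 h, and to -0.231 and -0.188 in the difference. Against these medians the projection neuron list stayed lower and the dopamine list stayed higher. The single genes that changed sign were named in advance and did not pass over all probes. At 2 h, Arc was 0.0977 in the deposited values, 0.104 with median scaling, 0.0394 in the centred values and 0.0127 without the 2 arrays of lowest weight, and Penk was 0.165, 0.17, 0.107 and, with the cortex covariate, 0.0597. In the deposited, median-scaled and centred values Arc lay below the median change of all probes. Penk lay below it in the deposited and centred values and above it with median scaling. With that covariate Ntrk2 was -0.373 at 2 h and -0.031 at 24 h, Bdnf -0.00557 and Fos -0.0151 at 24 h, and Egr1 0.00499 in the difference. At 24 h, Drd1 was -0.0206 in the deposited values, -0.0304 with median scaling, -0.0276 in the centred values and -0.0218 with slide position. Fos was -0.0158 with median scaling, -0.0535 with array weights, -0.0642 with slide position and -0.312 on slide 3, where Arc was -0.428 and Ntrk2 -0.0743. Ntrk2 was -0.0352 with array weights, and Penk was -0.0347 on slide 2. In the difference, Arc was -0.00481 in the deposited values and -0.0301 with median scaling. Ntrk2 was -0.208 and -0.223 there, -0.28 with array weights, -0.0871 with slide position, -0.157 in the centred values and -0.231 without the 2 arrays of lowest weight. Without each array in turn, Arc ran from -0.233 to 0.0108 at 2 h and from -0.0871 to 0.258 at 24 h, Ntrk2 from -0.106 to 0.198 at 2 h, from -0.112 to 0.173 at 24 h and from -0.145 to 0.179 in the difference, Drd1 from -0.0365 to 0.0749 and Fos from -0.123 to 0.122 at 24 h, and Egr1 from -0.069 to 0.0747 in the difference. Over all single genes and lists and all alternatives, 4146 values kept direction and side of the threshold, 148 no longer passed, 25 newly passed and 71 changed sign. The 4146 include genes that passed neither as planned nor in the alternative, so they do not measure how stable the calls are. These 71 include changes in the settings where the median of all probes shifted, which need not be changes relative to other probes. Genes near background, such as Pnoc and Hba-a3, are limited by the signal over background, since 8208 to 10306 of 22523 probes were detected per array.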

Other observations

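In this part, the cortex covariate and its tests of the 4 named genes and of lists, the test of the endothelial list, the permutation within slides and the splits with separate fits were chosen after the result was seen.

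With the mean of the cortex markers as a covariate, some log2 changes at 2 h shrank, some hardly moved and some grew. Cck went from 1.69 to 0.13 and Bdnf from 0.68 to 0.21, while Neurod6, itself part of that mean, went from 1.20 to 0.07. Adcyap1 (0.70 and 0.27), Efhd2 (0.82 and 0.48), Vip (1.32 and 0.94) and Drd1 (-0.38 and -0.30) lay between. Nr4a3 (0.60 and 0.63) and Nr1d1 (-0.47 and -0.45) moved little, and Crem (0.53 and 0.61), Pdyn (0.51 and 0.55) and Fst (0.99 and 1.17) grew. At the preset correlation the neuropeptide list still passed with it (adjusted p = 0.000532), as did the ER stress list (0.00819), and heat shock proteins (0.00308) and thalamus and pallidum markers (0.0478) newly passed. With an estimated correlation 0 lists passed, and the adjusted p was 0.231 for neuropeptides and thalamus and pallidum markers and 0.247 for ER stress and heat shock genes. Of the lists that had passed at 2 h, CREB target and trophic genes (0.0904), synaptic vesicle and release genes (0.354), projection neuron markers (0.384) and the cortex markers themselves (0.766) no longer passed at the preset correlation.

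Cortex markers were higher at 2 h in METH samples. More cortex tissue in those dissections may be a candidate explanation: the 100 probes that followed the marker mean most closely on slides 2 and 3 had a median of observed over predicted change of 0.412 at 2 h, 66 with the predicted sign, between the bounds set in advance, and 1000 random sets of 100 probes gave -0.51 to 0.875. It cannot be told apart from a METH effect on cortex-marker genes within the striatum. The probes were chosen for following the mean on the same arrays that gave the prediction, which can make the ratio too low. Nor does the range of random sets, which holds that value, separate these explanations. For the 4 named genes the values argue against more cortex tissue as the whole cause, since each kept at least 0.983 of its log2 change with the covariate. Nmu (1.42, SE 0.197, adjusted p = 0.00138) and Fst (1.17, SE 0.176, adjusted p = 0.0025) still passed, while Pnoc (0.92, SE 0.209, against 0.91, SE 0.176) and Nts (1.41, SE 0.295, against 1.28, SE 0.251) had an adjusted p of 0.164 and 0.0911 with larger standard errors.

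Haemoglobin genes were lower at 24 h, with a mean within-slide log2 change of -1.78 on slide 2 and -1.59 on slide 3. Relabelling METH and saline within slides gave a two-sided exact permutation p of 0.005, the smallest it can give. Each slide holds 3 METH and 3 saline arrays, so a difference in level between slides could not by itself produce this fall, which was present on both. Fewer vessels in the METH samples are not borne out, since the 15 endothelial and pericyte markers had a median log2 change of 0.00472 (quartiles -0.06 and 0.12) against -1.72 for the haemoglobin genes. Less blood in the METH samples may be a candidate explanation and cannot be told apart from a change in haemoglobin transcripts of brain cells. The blood markers other than globins had a median of -0.0754, above the bound set in advance, but that bound left out their errors: the intervals of 2 SE, -0.316 to 0.07 for Epb42 and -0.332 to 0.27 for Pf4, reach past it. Neither was detected on all 12 arrays, with saline levels 0.58 and 0.86 above undetected probes, so a fall could have shown in part and Pf4 (-0.03) showed none.

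For the counts of probes and lists, the METH and saline labels were split anew within slides 100 times, the real split included. At 24 h, 1 split gave 5 probes or more and the highest of the others gave 1, which argues against chance for that count. The real split is 1 of the 100, so a smaller share cannot be shown. Of the 5 probes, 4 are haemoglobin genes that vary together and the other follows Rps9, so they are not separate events. At 2 h, 6 splits gave 7 probes or more and the highest of the others gave 33, several times the real count. Whether this reflects a structure of the samples was not tested, and the shared spread, too small for slide 1, adds false calls. With separate fits of the 12 arrays of slide 1, 7 of the same splits gave the real count of 1 or more, and the highest of the others gave 9. The difference between the times had 0 probes, a count that any split reaches, so the splits test nothing there (3 was the highest of the others). Lists at 2 h numbered 6, a count reached by 15 splits, with 13 as the highest of the others. Lists at 24 h numbered 4, a count reached by 57 splits, with 11 as the highest of the others. Lists in the difference numbered 7, a count reached by 12 splits, with 12 as the highest of the others. Chance is not excluded for the probes at 2 h or for these counts of lists.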
